A study of Arabidopsis thaliana with 8 samples.

How the data were processed

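Transcript levels were measured with the Affymetrix ATH1 array, a 3' expression array for Arabidopsis thaliana, in 8 samples of seedlings of the Columbia accession. Per the labels, chilled seeds (5 days at 6 degrees C) germinated on 0.8% agar after 1 h of white light and were then kept in darkness for 3 days, both at 22 degrees C, before total RNA was taken with a column kit. The samples were grouped by the genotype in their titles into wild type (WT), the phyA-211 mutant of phytochrome A, the phyB-9 mutant of phytochrome B and the phyA-211 phyB-9 double mutant, written phyA, phyB and phyAphyB below, with 2 arrays each. No label says whether the 2 arrays of a genotype came from separate seed batches or cultures, so the p-values measure only the spread between these arrays, which may be technical. In the phyA group 1 title carries no replicate number, and that array is called replicate 1 in accession order.

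The deposited values are intensities on a linear scale, 1 whole number per probe set and array, made by the authors from the scanned arrays. The software that summarised the probes is not given in the sources used here. The 2% trimmed mean of each array lay between 2500.2 and 2500.3, so the deposited intensities had been scaled to a common mean. The 8 arrays cover 22810 probe sets, of which 64 are Affymetrix controls. The controls were left out of all comparisons and used to describe the arrays. The number of arrays, 2 per genotype, limits the precision of every comparison.

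Intensities were used as deposited, without further normalization, because the trimmed means differed by under 5%, the limit set before the data were examined. As the deposited values had been scaled to that mean, this check could not show whether the distributions were alike. Median intensities without controls still differed, at 605.5 to 753 in the replicate 1 arrays and 804 to 898 in the replicate 2 arrays. A pseudocount of 39, the 10th percentile of all values of the 22746 probe sets without controls, was added before taking log2. Changes are therefore on the log2(intensity + 39) scale, which understates changes of dim probe sets. The 40% of probe sets with the lowest mean log2 value over the 8 arrays were left out, and 13647 were kept. limma 3.58.1 (R 4.3.3) fitted a mean per genotype to all 8 arrays (lmFit, contrasts.fit, eBayes with an intensity trend). The residual spread had 4 degrees of freedom, and the prior added 5.87. Each of the 3 mutants was compared with WT and the double mutant with each single mutant. The interaction contrast asked whether the change in the double mutant differed from the sum of both single mutants' changes, and a moderated F test asked whether any genotypes differed. Tests were two-sided, and a probe set was called at an adjusted p (Benjamini-Hochberg) under 0.05. In simulated data with the measured means and spreads, 67.8% of probe sets changed by 2 log2 units and 96.8% of those changed by 3 were recovered for phyA against WT over 13647 probe sets, and 3.6% of those changed by 1. Simulated arrays varied independently. In the measured data, deviations from the group means in arrays of the same replicate number were correlated at up to 0.64. The recovery rates therefore need not hold for the measured arrays.

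Probe sets were named only through the platform's annotation table, whose Entrez numbers were matched to the RefSeq gene table of TAIR10.1. Of the 22746 probe sets, 13513 named 1 gene, 503 named several genes and 8730 were not listed, which leaves them without a name here and does not mean that they match no gene. Of the 13513, 13436 were found in the gene table. No probe set in the annotation table named PHYA or PHYB, so the level of the mutated genes could not be read by name. No coordinates are given, because no source names the genome build behind the probe sets. The rule for named genes was fixed before the data were examined. It took PHYA and PHYB, the 8 largest changes in each direction among called probe sets naming exactly 1 gene with both mutant arrays beyond both WT arrays, and the 3 members with the smallest p of each gene list with a call. If fewer than 3 passed, the 5 probe sets naming 1 gene with the smallest p were taken and given as not called. Probe sets without a name, and members of small lists, were added after their values were seen.

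Gene lists were also fixed before the data were examined, 24 in all. They covered photosynthesis, light signalling, hormones, growth, stress and reserve use, with lists for other tissues and handling as checks, and 3 were taken by rule: plastid-encoded genes, mitochondrion-encoded genes and cytosolic ribosomal proteins. Mitochondrion-encoded genes were taken by their symbols in the annotation table. Only 72 of the 480 written list members had a probe set of their own. Lists with at least 5 measured members, 1 probe set per gene, were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 6 lists and 4 contrasts (24 tests). In 10 simulations, a shift of 0.5 given to the 69 plastid-encoded genes in phyB was called in 10. Simulated genes varied independently, whereas the estimated correlation among these genes was 0.50 in the measured data. The simulation therefore does not show that the preset correlation is sound here. Another 14 lists had 1 to 4 measured members and are described only, and 4 had none, among them the ribosomal list, because the tables used give no gene descriptions.

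Alternatives fixed before the data were examined were a pseudocount of 1 or of the 25th percentile (189), quantile normalization, median centring, no filter or a filter of 60%, eBayes without a trend, array weights, fits on the compared groups alone, the replicate number as a block, leaving out each array in turn, and for lists an estimated correlation or ranks. Chosen after seeing the data were leaving out both arrays with the highest GAPDH 3'/5' ratios, that ratio as a covariate, the same 6 arrays as in the block fit without the block, the replicate number as a block over all 8 arrays, fits of 4 arrays against 4 with and without that block, and families of genes that share the letters of their symbol.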

Results

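The series profiled transcripts of dark-grown Arabidopsis seedlings that lack phytochrome A, phytochrome B or both. Phytochromes are the red and far-red light receptors of plants, and the seedlings had seen 1 h of white light before 3 days of darkness. There were 2 arrays for each of WT, phyA, phyB and phyAphyB, 8 in total. The 2% trimmed mean intensity was 2500.2 to 2500.3 on all 8 arrays, and 87.0% to 92.7% of probe sets lay above the pseudocount of 39. Neither mutated gene had a named probe set, so the genotype labels could not be checked on PHYA or PHYB by name.

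By median correlation, arrays of a genotype did not resemble each other more than arrays of different genotypes. The correlation of log2 values was 0.900 to 0.925 for the 4 pairs of the same genotype (median 0.913) and 0.837 to 0.976 for the 24 pairs of different genotypes (median 0.916). The highest value, 0.976, joined phyA replicate 1 and phyB replicate 1. The 3'/5' ratios of control transcripts, which are high where RNA was degraded or labelled mostly at its 3' end, differed between arrays. The GAPDH ratio was 16.7 in WT replicate 1 and 7.87 in phyB replicate 2, against 1.31 to 2.31 in the other 6 arrays. The actin ratio was 46.7 in WT replicate 1 and 3.64 to 10.8 in the others. Hybridisation spikes in WT replicate 1 were 3.02 times their level in the median array, and those in phyB replicate 2 1.84 times.

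**Figure D1:**
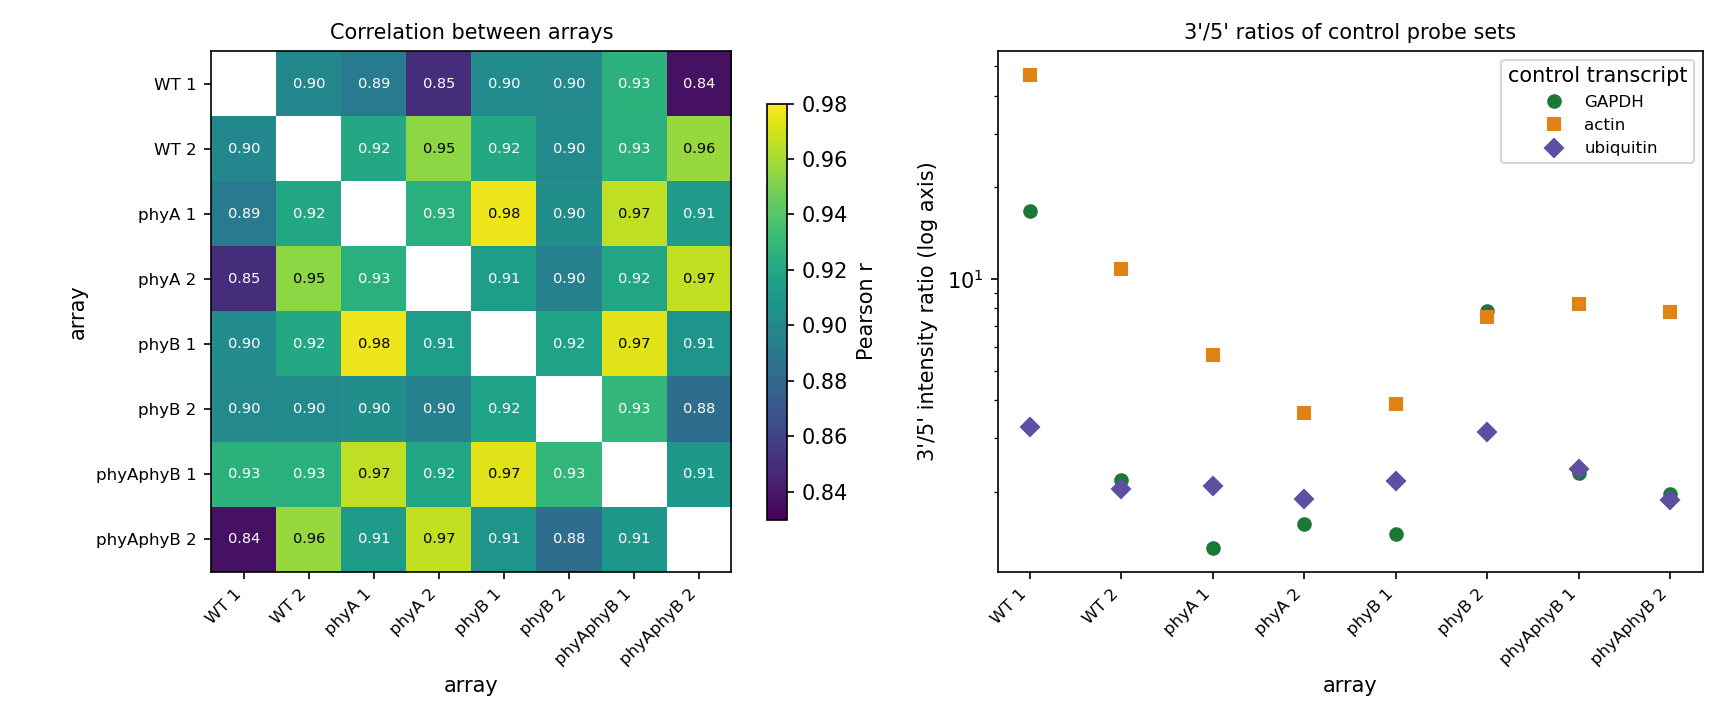
Left, Pearson correlation of log2 values between the 8 arrays over the 13647 probe sets kept, as colour and number. Right, 3'/5' intensity ratios of GAPDH, actin and ubiquitin control probe sets per array on a log axis, with WT replicate 1 highest for all 3 transcripts and phyB replicate 2 at 7.87 for GAPDH.

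In seedlings without phytochrome A, 2 probe sets differed from WT, and neither has a gene name in the tables used. Probe set 264508_at fell by 7.47 on the log2 scale (SE 0.69, limma adjusted p = 0.0056), from 15.05 ± 0.02 in WT to 7.58 ± 1.76 in phyA (SD, n = 2). Its change was -6.23 without phyA replicate 2 and -8.71 without phyA replicate 1. Its intensities in those arrays were 415 in phyA replicate 1 and 42 in phyA replicate 2. The latter lay close to the pseudocount of 39, so the size of this change depends on the pseudocount. Probe set 248066_at rose by 6.48 (SE 0.42, adjusted p = 0.00042), from 5.94 ± 0.38 to 12.42 ± 0.05 (SD, n = 2). Its WT intensities of 12 and 35 lay under the pseudocount of 39, so the size of its change depends on the pseudocount and is given without a fold. Both values separated all phyA-211 arrays from all others: 264508_at was 5.88 to 8.83 in the 4 arrays carrying phyA-211 and 14.00 to 15.06 in the other 4, and 248066_at was 11.86 to 12.46 against 5.67 to 6.60. At an unadjusted p under 0.05 there were 869 probe sets, 553 higher and 316 lower, where 682.35 would be expected with no change.

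**Figure D2:**
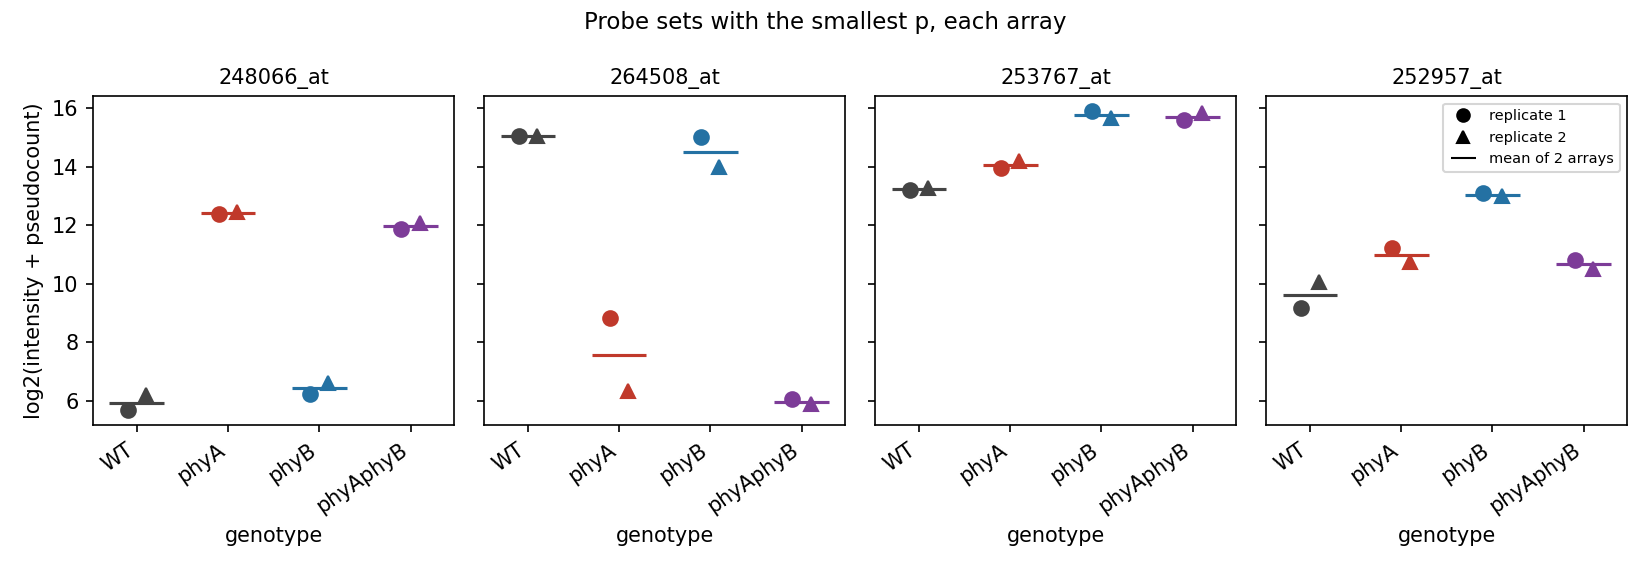
Log2(intensity + 39) of 4 probe sets without a gene name in each array, with replicate 1 as circles, replicate 2 as triangles and the mean of both arrays as a line for each genotype. Probe set 264508_at is low and 248066_at high in phyA and phyAphyB, while 253767_at is high in phyB and phyAphyB and 252957_at is highest in phyB.

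No probe set with a single named gene passed the test for phyA against WT. The 5 with the smallest p had limma adjusted p = 0.76 each. They were psbC, a plastid-encoded subunit of photosystem II, with a change of 2.31 (SE 0.49), and AT3G55920, a cyclophilin-type protein, at -1.80 (SE 0.38), with AT1G61840 at -2.05 (SE 0.41), AT2G02610 at -2.28 (SE 0.46) and AT3G26550 at -2.09 (SE 0.45). Among light harvesting genes, LHCB4.2, a minor antenna protein of photosystem II, stood at 1.59 (SE 0.37). Of the gibberellin receptor genes, GID1B stood at 2.29-fold of WT and GID1A at 1.81-fold, and GID1C was higher by 0.59 on the log2 scale, none of them called. Of the 4 measured genes in the gibberellin list, 3 were higher in phyA and 1 was lower, at a log2 change of -0.61. In phyB the 4 log2 changes lay between 0.06 and 0.29. The log2 change of the dehydrin LTI30 was -1.21. The count rested on WT replicate 2. Without it, which leaves WT replicate 1 with its GAPDH ratio of 16.7 as the WT array, 93 probe sets were called, 91 of them higher. Leaving out any other single array gave 2 calls, and leaving out both arrays of high GAPDH ratio gave 1.

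Plastid-encoded genes as a group stood higher in phyA than in WT. Of 69 measured, 64 had a positive change, with a median of 0.70 (camera adjusted p = 5.4e-10, and adjusted p = 0.52 with an estimated correlation). No single member was called, either over all probe sets or adjusted over the list alone, where 0 passed. The median per array, relative to the mean of both WT arrays, was 0.15 in phyA replicate 1 and 1.19 in phyA replicate 2, beside -0.16 and 0.16 in WT. Without phyA replicate 2 the median change was 0.15. The 22 photosystem genes had a median of 1.18 (0.59 in phyA replicate 1 and 1.73 in phyA replicate 2), with psbC at 2.31 and psbJ at 2.24 (1.25 without WT replicate 1, and called at 3.22 without WT replicate 2, adjusted p = 0.045). Mitochondrion-encoded genes had a median of 0.57 (11 of 12 positive, adjusted p = 0.012). With an estimated correlation their adjusted p was 0.53, and without phyA replicate 2 (0.080) or WT replicate 2 (0.33) they were not called at the preset correlation either, at medians of 0.31 and 0.41. The nuclear photosystem and light harvesting list was not called (median 0.32, adjusted p = 0.16), but it was with quantile normalization (0.38, adjusted p = 0.020), without WT replicate 1 (0.56, adjusted p = 0.00089) and without phyA replicate 2 (0.59, adjusted p = 0.014). Chlorophyll synthesis genes, with 7 of 8 changes positive, had a median of 0.24, cell wall expansion genes 0.30 and reference genes -0.32, and none of these 3 lists was called. Without 1 array the medians ran from 0.24 to 0.45 (without phyA replicate 1), from 0.06 (without WT replicate 1) to 0.58 (without WT replicate 2) and from -0.39 to -0.25.

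In seedlings without phytochrome B no probe set passed the limma test against WT (smallest adjusted p = 0.056), with 809 at an unadjusted p under 0.05, 531 higher and 278 lower. The smallest p belonged to 252957_at, at 3.43 (SE 0.40), and 253767_at, at 2.56 (SE 0.30), both unnamed here. Of the named genes, none called, PDF2.1, a plant defensin, stood at 2.41 (SE 0.49), AT3G55920 at -2.02 (SE 0.38), AT3G59340 at -2.63 (SE 0.47), AT5G45350 at 1.80 (SE 0.33) and AT2G27580 at 1.75 (SE 0.36). PDF2.1 was 12.29 and 12.51 in the phyB arrays, 11.67 and 10.99 in the double mutant, and 9.31 to 10.69 in the other 4 arrays. Leaving out WT replicate 2 gave 70 calls, all higher. With no filter, with 60% of probe sets left out, or with the replicate number as a block over all arrays, 2 were called.

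Plastid-encoded genes were higher in phyB than in WT by a median of 0.77, with 65 of 69 positive (camera adjusted p = 1.1e-13, and adjusted p = 0.52 with an estimated correlation). psbC stood at 1.85, petB at 1.44 (0.81 without WT replicate 1, and called at 2.06 without WT replicate 2, adjusted p = 0.045) and rpoC1 at 1.28 (0.85 without phyB replicate 2). This list depended on phyB replicate 2, where its median was 1.51 against 0.04 in phyB replicate 1. Without that array the median was 0.04 and the list was not called (adjusted p = 0.39). Mitochondrion-encoded genes had a median of 0.83, with 12 of 12 positive (adjusted p = 5.9e-06, and adjusted p = 0.52 with an estimated correlation). Without phyB replicate 2 their median was 0.19 and they were not called (adjusted p = 0.29). The nuclear photosystem list had a median of 0.37 with 5 of 7 positive (adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation). It was led by LHCB4.2 at 1.42, PSBY at 1.01 and LHCB4.1 at 0.76 (0.48 without phyB replicate 2), and 2 members passed when adjusted over the list alone against 0 over all probe sets. That list was not called without WT replicate 2 (median 0.13, adjusted p = 0.33) or phyB replicate 2 (median 0.48, adjusted p = 0.053), or with ranks (adjusted p = 0.073). The phyB replicate 2 array also had the GAPDH 3'/5' ratio of 7.87. Chlorophyll synthesis genes (median -0.02, mean 0.02), cell wall expansion genes (0.09) and reference genes (-0.29) were not called, except that cell wall expansion genes were without WT replicate 2 (0.23, adjusted p = 0.027). Without phyB replicate 1 the 3 medians were -0.25, -0.05 and -0.50, without phyB replicate 2 the first 2 were 0.29 and 0.39, and without WT replicate 1 that of reference genes was -0.18.

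**Figure D3:**
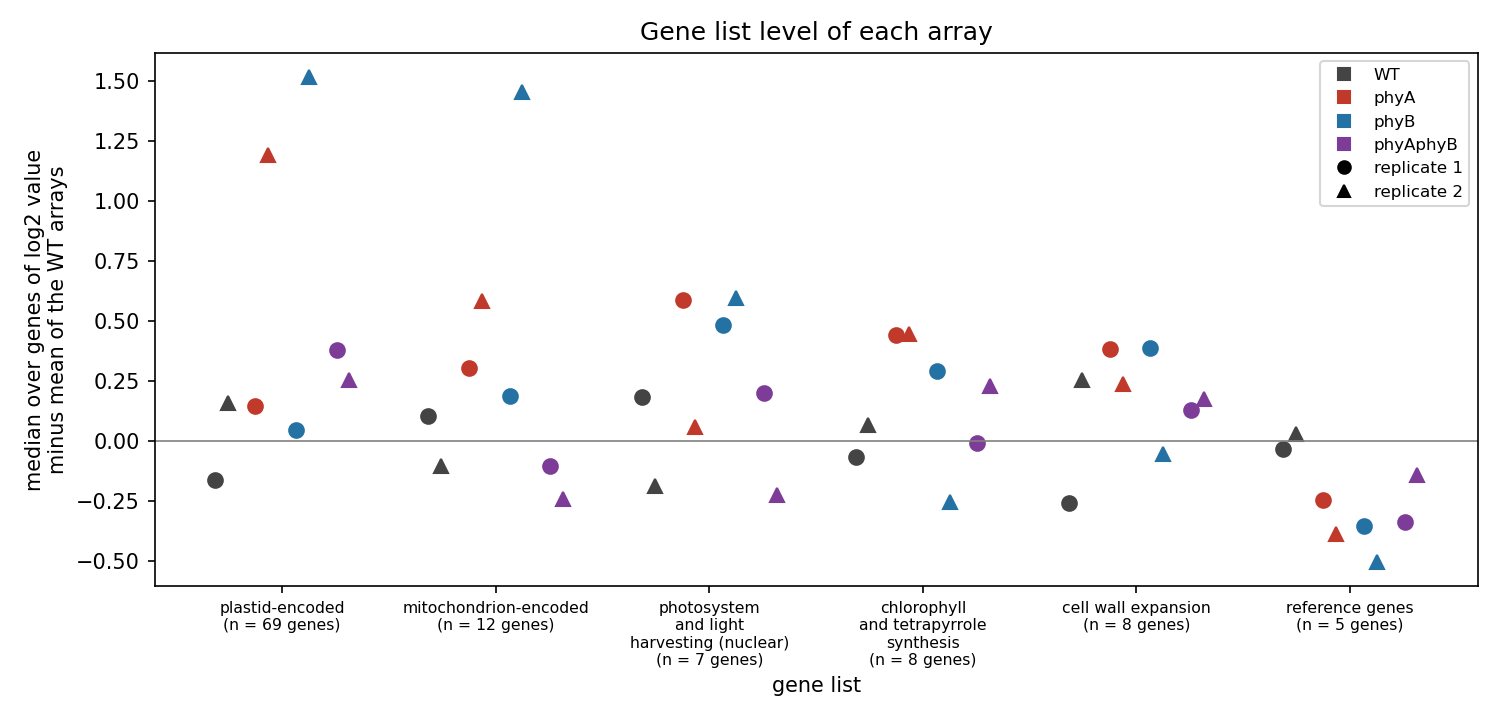
Median over the genes of each tested list of the log2 value minus the mean of the WT arrays, for each array, coloured by genotype, with circles for replicate 1 and triangles for replicate 2. For plastid-encoded genes phyA replicate 2 (1.19) and phyB replicate 2 (1.51) lie above the other arrays, which lie between -0.16 and 0.38.

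The double mutant differed from WT at 3 probe sets by limma, all without a gene name. Probe set 264508_at fell by 9.08 (SE 0.69, adjusted p = 0.00092), 248066_at rose by 6.03 (SE 0.42, adjusted p = 0.00084) and 253767_at rose by 2.49 (SE 0.30, adjusted p = 0.048). The intensities of 264508_at in the double mutant, 28 and 20, lay under the pseudocount, as did those of 248066_at in WT. The sizes of both changes depend on it. The call of 253767_at was lost with a pseudocount of 1, median centring, no filter or no trend, with adjusted p from 0.072 to 0.52 at changes of 2.37 to 2.50. It was also lost without any 1 of the 8 arrays other than WT replicate 2, with adjusted p up to 1.00 at changes of 2.36 to 2.62. At an unadjusted p under 0.05 there were 487 probe sets, below the 682.35 expected with no change. Of the named genes, none called, PAP85, a vicilin-like seed storage protein, stood at 1.68 (SE 0.45), with AT1G54870 at 2.57 (SE 0.70, 1.55 without WT replicate 1), AT2G19970 at -1.96 (SE 0.39), AT5G57785 at -1.59 (SE 0.41) and AT3G61930 at -1.31 (SE 0.35). PAP85 was 13.59 and 14.60 in phyB, 13.79 and 14.30 in the double mutant and 12.12 to 13.12 in WT and phyA. Without WT replicate 2 there were 30 calls, 29 higher, and with both arrays of high GAPDH ratio left out there was 1.

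Plastid-encoded genes were higher in the double mutant by a median of 0.28, with 56 of 69 positive (camera adjusted p = 0.00080, and adjusted p = 0.62 with an estimated correlation), with psbJ at 2.12, psaJ at 1.02 and petB at 1.01. Without WT replicate 1 psbJ was 1.14 and petB 0.39, and without phyAphyB replicate 1 psaJ was 0.55. The median was 0.17 without WT replicate 1 and 0.47 without WT replicate 2, with the list called in both. Mitochondrion-encoded genes had a median of -0.04 with 6 positive and 6 negative, and nuclear photosystem genes a median of -0.01. Neither list was called, although mitochondrion-encoded genes were with no filter (-0.43, adjusted p = 0.0039), nor were chlorophyll synthesis genes (0.14, 8 of 8 positive), cell wall expansion genes (0.12) or reference genes (-0.31). Without 1 array these 3 ran from -0.01 (without phyAphyB replicate 2) to 0.28 (without WT replicate 2), from -0.03 (without WT replicate 1) to 0.40 (without WT replicate 2) and from -0.34 to -0.14 (without phyAphyB replicate 1).

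Against phyA, the double mutant had no called probe set by limma, with 107 at an unadjusted p under 0.05, below the 682.35 expected with no change. Against phyB it had 2, with 147 at an unadjusted p under 0.05. Counts below that expected, here and in other contrasts, can arise where a fit takes differences shared by arrays across genotypes as spread. Such shared differences were present. Deviations from the group means in arrays of the same replicate number were correlated at 0.60 for phyA and phyAphyB and at 0.15 for phyB and phyAphyB. A comparison of the replicate 1 with the replicate 2 arrays called 876 probe sets by limma. How far this lowered the counts was not tested, so few calls do not show that genotypes were alike. Probe set 248066_at rose by 5.54 (SE 0.42) and 264508_at fell by 8.53 (SE 0.69), each with an adjusted p of 0.0016. Without phyB replicate 1 the changes were 5.37 (adjusted p = 0.058) and -8.03 (adjusted p = 0.13), and 5 probe sets were called with only the arrays of phyB and phyAphyB in the fit. The moderated F test over the 4 genotypes called 2 probe sets, and without WT replicate 2 it called 21.

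No probe set passed the interaction test (451 at an unadjusted p under 0.05 by limma, below the 682.35 expected, and 16 calls without WT replicate 2). At the level of lists, the changes in the double mutant lay below the sum of those in the single mutants. The median interaction was -1.13 for plastid-encoded genes (65 of 69 negative, camera adjusted p = 2.2e-17), -1.46 for mitochondrion-encoded genes (12 of 12 negative, adjusted p = 2.3e-11) and -0.70 for nuclear photosystem genes (6 of 7 negative, adjusted p = 0.00018). All 3 had an adjusted p of 0.52 with an estimated correlation. The plastid-encoded median was -1.89 without phyB replicate 1 and -0.33 without phyB replicate 2, and the mitochondrion-encoded median -2.11 and -1.06. The nuclear photosystem median was -1.12 without WT replicate 1 and -0.47 without WT replicate 2. All 3 medians stayed negative without any 1 array. For the organelle lists this is a weak check, since it always keeps phyA replicate 2 or phyB replicate 2. In the replicate 1 arrays the plastid-encoded medians were -0.16 in WT, 0.15 in phyA, 0.04 in phyB and 0.38 in phyAphyB. In the replicate 2 arrays they were 0.16, 1.19, 1.51 and 0.25 in that order, so the negative interaction came from the replicate 2 arrays. Cell wall expansion genes (median -0.36), chlorophyll synthesis genes (-0.09) and reference genes (0.24) were not called, except that cell wall expansion genes were without WT replicate 2 (-0.51, adjusted p = 0.027). Without 1 array these 3 ran from -0.57 (without phyB replicate 2) to -0.22 (without WT replicate 1), from -0.43 (without phyB replicate 2) to 0.17 (without phyB replicate 1) and from 0.16 (without phyA replicate 2) to 0.32. The median interaction over all probe sets was 0.12 with the intensities as deposited and -0.02 after median centring. Among members, psbC stood at -3.25 (SE 0.69), LHCB4.2 at -2.38 (SE 0.52) and nad5 at -2.03 (SE 0.63). Both organelle lists were highest in phyA replicate 2 and phyB replicate 2. The mitochondrion-encoded median was 0.31 in phyA replicate 1, 0.58 in phyA replicate 2, 0.19 in phyB replicate 1 and 1.45 in phyB replicate 2, beside 0.10 and -0.10 in WT. AT3G55920 had an interaction of 2.74 (SE 0.54) and the subtilase gene ATSBT5.2 2.11 (SE 0.49), neither called.

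The changes of the 3 mutants against WT were correlated across probe sets, which are not independent replicates and share the WT arrays. The correlation was 0.64 between phyA and phyB, 0.82 between phyA and phyAphyB and 0.64 between phyB and phyAphyB. Unchanged simulated groups that shared a simulated control gave 0.50, which follows from their equal group sizes and spreads. The covariance was 0.193, 0.226 and 0.169 in the same order, against 0.111 simulated, and the spread between the WT arrays alone would give 0.154. Both probe sets called in phyA were also called in phyAphyB in the same direction, 1 higher and 1 lower, where independent lists would share 0.00015 and 7.3e-05. The simulation, in which no probe set was changed, shared 0. Neither sets a benchmark for the shared calls. Unchanged data give almost no calls to share, and both mutants carry phyA-211 and were compared with the same WT arrays. No overlap with phyB could be counted, since phyB had 0 calls. Splitting the controls would leave 1 WT array for each comparison, so part of the excess may come from the shared controls.

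Lists with under 5 measured members held 31 genes, none of them called over all probe sets in any contrast. Values against WT are given for phyA, phyB and phyAphyB in that order. The auxin-responsive gene IAA29 stood at -0.36, -0.57 and -0.54, and the clock gene GI at -0.09, -0.19 and 0.17. Rubisco activase (RCA) stood at 1.01, 0.71 and 0.97, and isocitrate lyase (ICL), a glyoxylate cycle enzyme used when seed oil is mobilised, at 0.46, 1.00 and 0.31. Of the 3 measured carbon fixation genes, RCA among them, 1, 2 and 1 were higher than in WT. Of the 3 storage lipid mobilisation genes, ICL among them, 2, 1 and 2 were higher. FHL, which carries phytochrome A into the nucleus, stood at -0.10, -0.08 and -0.37. EIN3, an ethylene response regulator, stood at -0.38, -0.80 and -0.09, and UGT78D1, a flavonol glycosyltransferase, at -0.47, 0.59 and 0.23. As checks of tissue make-up, stage and handling, the root hair expansin EXPA7 stood at 1.53, 1.74 and 1.28, the root beta-glucosidase PYK10 at -0.26, 0.11 and -0.20, the late embryogenesis gene LEA4-5 at 0.36, 0.13 and -0.33, the heat shock co-chaperone Fes1A at -0.06, 0.17 and 0.35, the histone gene HTB1 at 0.37, 1.03 and 0.63 and the zinc finger gene STZ at 0.59, 1.15 and 0.75. Of the 3 measured genes in the list of HTB1, only 1 was higher in each mutant. Adjusted over the list alone, 1 gene passed in phyA (LTI30) and 3 in phyB (HTB1, EXPA7 and STZ, the last alone in its list).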

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

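All tests of explanations in this part were chosen after the results were seen. The interaction term stood out because it was called on 3 gene lists at the preset correlation. A called interaction does not by itself show a change in the double mutant. Against WT the medians in phyAphyB were -0.04 for mitochondrion-encoded and -0.01 for nuclear photosystem genes, neither called in the main test. The median interaction was -1.13 for plastid-encoded genes, -1.46 for mitochondrion-encoded genes and -0.70 for nuclear photosystem and light harvesting genes, negative in 65 of 69, 12 of 12 and 6 of 7 genes. With an estimated correlation none of these 3 was called (adjusted p = 0.52 each). The 5S ribosomal RNA control probe set, which no comparison uses, read 1815 in phyB replicate 1 and 4311 in phyB replicate 2, above 881 and 1023 in WT. It read 530 and 2649 in phyA and 870 and 1069 in the double mutant.

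Organelle-encoded transcripts were highest in phyA replicate 2 and phyB replicate 2. Bias toward the 3' end of transcripts is argued against for phyA replicate 2, where 0 of the 5 control 3'/5' ratios lay above the median of the 8 arrays, but stays open for phyB replicate 2, where 4 of the 5 did and without which, and without WT replicate 1, the plastid-encoded and mitochondrion-encoded medians in phyB were -0.14 and 0.34, neither called, although WT replicate 1 and phyAphyB replicate 1, with 5 of the 5, had plastid-encoded medians of only -0.16 and 0.38. A larger share of RNA without a poly(A) tail in the labelled sample may account for the pattern, as the plastid-encoded median went with the log2 5S ribosomal RNA signal over the 8 arrays (Pearson r = 0.82, exact permutation p = 0.016, adjusted p = 0.049 over 4 relations, and Spearman rho = 0.52, exact permutation p = 0.20, adjusted p = 0.24). It stays open, since r was -0.13 without phyA replicate 2 and phyB replicate 2, while with the 25S ribosomal RNA probe set, at intensities of 12 to 126, r was 0.60 (p = 0.12, adjusted p = 0.15), rho 0.76 (p = 0.037, adjusted p = 0.15) and r without phyB replicate 2 and phyAphyB replicate 2 0.81, and mitochondrion-encoded genes had r = 0.76 with 5S (adjusted p = 0.049, -0.23 without the same 2 arrays) and 0.56 with 25S (adjusted p = 0.15, 0.067 without its 2). An effect of genotype stays open too: 2 of the 4 single mutant arrays lay above both WT arrays in the plastid-encoded median and 4 of the 4 in the mitochondrion-encoded median, where phyB replicate 1 exceeded the higher WT array by 0.084, under the 0.21 between the WT arrays.

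WT replicate 1 had the lowest mean correlation with the other 7 arrays, 0.887, where the other arrays had 0.905 to 0.936. A distribution of values left uneven by the deposited scaling is argued against, since the mean correlation was 0.884 after quantile normalization. A phyA-211 plant labelled as WT is argued against as well, since 264508_at, the probe set lowest in phyA-211 arrays when chosen without this array, lay 6.24 log2 units above the highest phyA-211 array in it. Bias toward the 3' end may account for the difference, as 5 of the 5 control 3'/5' ratios were highest in this array. No biological explanation was tested, because the difference lies within 1 genotype.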

How the results depend on the processing

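Leaving out both arrays of high GAPDH ratio, the GAPDH ratio as a covariate, the fit of 6 arrays without a block and the block over 8 arrays were chosen after seeing the data. Directions held for all called probe sets and list tests under the alternatives run, except that the median of plastid-encoded genes in phyB turned to -0.14 (adjusted p = 0.93) without both arrays of high GAPDH ratio. Of the list tests under alternatives, 427 stayed on their side of the threshold, 18 lost a call and 7 gained one. Of single probe sets 976 stayed, 19 lost a call and 14 gained one, and of counts 198 stayed within 1.5 times and 40 did not. Results that were not called in either fit are among those that stayed, so these numbers do not measure how well the calls held. Array weights came out equal within each pair of arrays, so that setting says nothing about stability. No alternative on the level of PHYA or PHYB was run, because neither has a named probe set. Dim probe sets are limited by the signal over background, since the pseudocount shrinks their changes.

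With a pseudocount of 1 or with 60% of probe sets filtered out, 248066_at was no longer among the tested probe sets. With a pseudocount of 1 the counts were 1 for any genotype, 1 for phyA against WT, 1 for the double mutant against WT, 1 against phyB and 1 for the overlap of phyA and phyAphyB. With the 60% filter they were 1 for any genotype, 1 for phyA against WT, 1 for the double mutant against phyB, 1 for the overlap of phyA and phyAphyB, 2 for phyB against WT and 1 for the overlap of phyB and phyAphyB. Without both arrays of high GAPDH ratio, which leaves fewer samples, they were 1 for any genotype, 1 for phyA against WT, 1 for the double mutant against WT, 1 against phyB and 1 for the overlap of phyA and phyAphyB. With that ratio as a covariate, phyA against WT gave 1 and its overlap with phyAphyB 1. With no filter phyB against WT gave 2, its overlap with phyAphyB 1 and named genes 2. The 25th percentile pseudocount gave 1 for the double mutant against phyA and 1 named gene. Quantile normalization gave 4 for any genotype, only the compared groups gave 5 for the double mutant against phyB, and a threshold of 0.1 gave 1 for the overlap of phyB and phyAphyB. Apart from the lost probe set and the fewer samples, the cause was not tested.

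Leaving out each array in turn, which assumes that a lone sample varies like the other groups, gave 2 to 21 calls for any genotype, 0 to 16 for the interaction, 2 to 93 for phyA against WT, 0 to 70 for phyB against WT and 2 to 30 for the double mutant against WT. The double mutant gave 0 to 2 against phyB, with 0 without phyB replicate 1. Named genes ran from 0 to 95, and the overlaps from 2 to 28 (phyA and phyAphyB), 0 to 53 (phyA and phyB) and 0 to 27 (phyB and phyAphyB). All these highest counts but that against phyB came without WT replicate 2, and the cause was not tested. Of the 93, 70 and 30 probe sets then called against WT, 2, 0 and 3 were also called with all arrays.

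Of the 24 list tests 9 were called, 0 with an estimated correlation, 8 with ranks and 6 to 10 without 1 array. The estimated correlation widened the test and left the medians as they were: -1.46, 0.57 and 0.83 for mitochondrion-encoded genes (interaction, phyA, phyB), -0.70 and 0.37 for nuclear photosystem genes (interaction, phyB) and -1.13, 0.70, 0.28 and 0.77 for plastid-encoded genes (interaction, phyA, phyAphyB, phyB), with adjusted p from 0.52 to 0.62. Ranks ended the call of nuclear photosystem genes in phyB (0.37, adjusted p = 0.073). Without both arrays of high GAPDH ratio mitochondrion-encoded genes in phyB were not called (0.34, adjusted p = 0.18). Without each array in turn the medians ran from 0.31 to 0.58 for mitochondrion-encoded genes in phyA, 0.19 to 1.45 in phyB, 0.13 to 0.81 for nuclear photosystem genes in phyB and from 0.045 to 1.51 for plastid-encoded genes in phyB. The calls were lost without phyB replicate 2 for the 3 lists in phyB, without WT replicate 2 for nuclear photosystem genes in phyB and mitochondrion-encoded genes in phyA, and without phyA replicate 2 for the latter.

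The replicate number as a block, on the 6 arrays of WT, phyB and phyAphyB, gave 0 calls for phyB against WT, 2 for the double mutant against WT and 2 against phyB, as many as the same 6 arrays without the block. As a block over all 8 arrays, with the phyA array without a number taken as replicate 1, it gave 7 for any genotype, 3 for phyA against WT, 2 for phyB against WT, 3 for the double mutant against WT, 0 against phyA, 2 against phyB, 0 for the interaction and 1 for the overlap of phyB and phyAphyB, and 9 list tests were called. Deviations from the group means in arrays of the same number were correlated at -0.06 for WT and phyB and at 0.15 to 0.64 for the other 5 pairs of genotypes. No label says that a number marks a shared batch or day, and not every pair of genotypes lay above 0.1, so the main comparisons have no block. Of the 8 arrays, 7 had their highest correlation with an array of the same number, and phyB replicate 2 had it with phyAphyB replicate 1 (0.929), so the numbers may still mark something the samples shared.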

Other observations

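All tests in this part were chosen after the results were seen. Alpha-expansin genes (EXPA), whose products loosen cell walls, stood higher in all 3 mutants when genes were grouped by the letters of their symbol. All 7 measured EXPA genes had positive changes in each mutant, with medians of 1.18 in phyA (camera adjusted p = 0.00021), 1.30 in phyB (3.8e-06) and 0.94 in phyAphyB (0.00037). With an estimated correlation the adjusted p was 0.88 for each of these tests and for the interaction. EXPA4 stood at 2.49, 2.01 and 1.53, EXPA8 at 1.21, 1.85 and 1.28 and EXPA7, of root hairs, at 1.53, 1.74 and 1.28, in the order phyA, phyB, phyAphyB. The interaction was negative for 7 of 7 (median -1.56, adjusted p = 8.0e-06), at -1.03 without WT replicate 1 and -2.09 without WT replicate 2. It is not independent of the comparisons with WT, since it adds the WT mean that each of them subtracts. Mutants that stand at similar levels above WT therefore give a negative interaction. No single gene was called over all probe sets. Adjusted over the family alone, 4 passed in phyA, 6 in phyB, 0 in phyAphyB and 0 for the interaction. The median per array, relative to the WT mean, was -0.53 and 0.53 in WT and 0.73 to 1.59 in the 6 mutant arrays. Without WT replicate 1, the array with the highest control 3'/5' ratios and the lowest mean correlation, the medians were 0.57, 0.72 and 0.32, and the call in phyAphyB was lost (adjusted p = 0.14). Without phyA replicate 1 the median in phyA was 0.73. The directions were the same as deposited, with quantile normalization and with median centring.

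Genes of the TBL family, which act in the acetylation of cell wall polysaccharides, were lower by a median of -0.34 in phyA (13 of 16 negative, adjusted p = 0.019) and -0.38 in phyAphyB (11 of 16, adjusted p = 0.019). With an estimated correlation the adjusted p was 0.88 for both. In phyB the median was -0.30 and the family was not called (adjusted p = 0.18). Without WT replicate 2 the medians were -0.41 and -0.26, with an adjusted p of 0.096 each. Without replicate 2 of the mutant they were -0.50 (adjusted p = 0.26) and -0.29 (0.096), and without WT replicate 1 the family was called in phyAphyB at -0.25. Another 4 families had 1 call each: autophagy genes (ATG) in phyAphyB at -0.58, RALFL signal peptide genes in phyA at -0.79, UGT glycosyltransferase genes in phyAphyB at 0.43 and PRA genes in phyB at 0.44. With an estimated correlation their adjusted p ran from 0.88 to 0.97. Without WT replicate 1 the ATG, RALFL and UGT medians were -0.08, -0.45 and 0.06 (adjusted p = 0.75, 0.60 and 0.45), and without WT replicate 2 the PRA median was 0.28 (adjusted p = 0.35). The calls were also lost without phyAphyB replicate 2 for ATG (-0.17, adjusted p = 0.60) and UGT (0.17, adjusted p = 0.54), without phyA replicate 2 for RALFL (-0.42, adjusted p = 0.55) and without phyB replicate 1 for PRA (0.37, adjusted p = 0.30). Without WT replicate 2 the ATG and RALFL medians were -1.11 and -1.24, and without phyAphyB replicate 1 the ATG and UGT medians -0.93 and 0.73, all called. With median centring the ATG, RALFL and PRA calls were lost (-0.70, -0.79 and 0.45, adjusted p = 0.052, 0.052 and 0.066), and with quantile normalization the RALFL call (-0.81, adjusted p = 0.052). Of 104 tests on 26 families 10 were called, and 0 with an estimated correlation (smallest adjusted p = 0.88).

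Among plastid-encoded genes, the 22 photosystem genes had medians of 1.18 in phyA, 0.93 in phyB and 0.84 in phyAphyB, at 0.59 and 1.73 in the 2 phyA arrays, 0.36 and 1.54 in the phyB arrays and 0.34 and 0.66 in the phyAphyB arrays, in the order of the replicate numbers. The 15 ribosomal protein genes stood at -0.31 and 1.18, -0.29 and 1.32 and 0.02 and 0.52 in the same arrays, and the 10 genes of the NDH complex at -0.08 and 0.82, -0.42 and 1.60 and 0.40 and -0.05, with opposite signs in the 2 arrays of a genotype in each case but ribosomal protein genes in phyAphyB. The WT arrays themselves stood at -0.26 and 0.26 for ribosomal protein genes and at 0.11 and -0.11 for NDH genes. ATP synthase, cytochrome, RNA polymerase and the remaining plastid-encoded genes were positive in both arrays of phyA and of phyB. In phyAphyB cytochrome and RNA polymerase genes had opposite signs in the 2 arrays. Differences between classes were not tested.

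When the 4 arrays carrying phyA-211 were compared with the other 4, 5 probe sets were called by limma, all unnamed here: 248066_at, 257809_at, 255500_at and 259224_at were higher and 264508_at lower. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many calls: this split itself, and the split of the 4 replicate 1 arrays from the 4 replicate 2 arrays, with 876. The split by replicate number need not be a chance outcome, so 2 of 35 cannot decide whether chance gave the number of calls. No split but these gave more than 2. Of single probe sets, 248066_at (adjusted p = 1.0e-06) was 11.86 to 12.46 in the 4 arrays and 5.67 to 6.60 in the others, and 264508_at (adjusted p = 3.0e-05) was 5.88 to 8.83 against 14.00 to 15.06. The 4 arrays carrying phyB-9 differed from the other 4 at 2 probe sets, 248125_at and 253767_at, both higher, the former by 2.11 (adjusted p = 0.010, 14.49 to 15.04 against 12.38 to 12.87). Here 3 of the 35 splits gave as many: this split itself, the phyA-211 split and the split by replicate number. The phyA-211 split is a genotype contrast and the split by number need not be a chance outcome. The count of splits therefore cannot decide on chance here either. No split other than these 3 called any probe set. The 876 calls by replicate number point to a structure of the samples that follows the replicate number, whose cause was not tested. With the replicate number as a block, and the phyA array without a number taken as replicate 1, the phyA-211 arrays differed at 5 probe sets, all 5 called before, and the phyB-9 arrays at 3, with 2 called before.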
